A study of Homo sapiens with 12 samples.

How the data were processed

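Granuloma annulare is an inflammatory skin disease in which macrophages and T cells gather around altered collagen in the dermis. RNA from lesional skin of 5 patients was sequenced before treatment and after 6 months of tofacitinib, an oral inhibitor of Janus kinases (JAK) given at 5 mg per dose, together with skin of 2 healthy people, which gives 12 libraries. Per the labels, total RNA was used for stranded paired-end libraries with 100-base reads. The genome build was hg38, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here, nor is whether reads in introns were counted or how strand was used. Reads of overlapping genes, antisense genes and near-identical copies, such as the late cornified envelope (LCE) genes, the tryptase genes TPSAB1 and TPSB2 and the complement genes C4A and C4B, therefore cannot be assigned with certainty.

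The authors deposited 1 table of 19882 genes in 12 columns. Its values were read here as log2 of RPKM plus 1, where RPKM is the number of reads scaled to the length of the gene in kilobases and to the total of the library. This differs from the name of the deposited file, which calls its values normalized counts, and was inferred from the values. The smallest positive steps fix base 2 and the offset of 1. Undoing the log and multiplying by each gene's whole span in the RefSeq annotation of GRCh38, introns included, gave multiples of 1 step per library, and that step gave each library's total. Between 73.8 and 75.8% of the low values of a library (up to 50 reads) came out within 0.05 of a whole read, where chance gives about 10%. The recovered totals were 13662465 to 41859977 reads per library. The remaining values did not come out whole, so recovered reads are approximate. A span was found for 19017 genes by symbol and for 482 by an older symbol, and 383 had none. The main design had been written for normalized counts. Since the values were on a log2 scale with an offset of 1, the deposited log2 values were tested as they stood, and the count filter was applied to recovered reads. Because the offset is large against the RPKM of long or weakly transcribed genes, log2 differences understate their change, and mean RPKM with its SD and the ratio of mean RPKM are given beside them.

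Column names gave the group and the patient number. The columns before treatment and of healthy skin carry names that match the sample titles, and the abbreviation of the after columns was assigned by elimination. The labels number the patients 1 to 5 in both patient groups, so these numbers pair the libraries of a person. The correlation of deviations from the group means was -0.01 to 0.59 within a patient (median 0.36), against a median of -0.14 between patients, and 4 of the 5 before libraries correlated best with the after library of the same patient. With the patient as a fixed block, 0 genes were called after against before treatment in limma. Each library comes from another person or another time, and p-values measure the spread between them. Genes of the sex chromosomes that would reveal a person's sex (20 genes) were left out of every table and test.

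Genes were tested with at least 10 reads, scaled to the median depth, in at least 2 libraries, which left 16857 genes. Of these 99 had no span and were kept with an RPKM of at least 0.25 in at least 2 libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3 over all 12 libraries with the group as the only term and moderated variances following a trend on the mean, two-sided, and p-values were adjusted with the Benjamini-Hochberg method. An adjusted p under 0.05 is called a change. The 3 comparisons were before treatment against healthy skin, after against before treatment, and after treatment against healthy skin. The patient as a block was an alternative, and the fixed block was fitted over the 10 patient libraries alone. Fixed before the data were examined were the groups, the tests, most alternatives, 39 gene lists with genes in the table and the rule for named genes. That rule takes, per comparison and direction, the 8 genes with the largest difference among called genes with a log2 difference of at least 1, a mean of at least 50 scaled reads in the higher group and no overlap between groups (for after against before, the same direction in all 5 pairs). It fills to 4 by the smallest p where fewer pass, and adds a panel of 24 cytokine, JAK, macrophage and matrix genes and up to 4 members with the smallest p from each list described. Genes named outside it are said to be so.

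Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over 117 tests (39 lists in 3 comparisons). The alternatives for lists were a correlation estimated from the data and fry. Camera compares the log2 differences of a list with those of all other genes, and with a preset correlation it takes the members as nearly independent. A list level is the mean of the deposited log2 values over its members in 1 library. These levels were compared with exact two-sided permutation tests, added after the first results: over the 252 arrangements of 5 against 5 libraries, where the smallest p is 0.00794, over the 32 sign changes of the 5 paired differences, where it is 0.0625, and over the 21 arrangements of 5 against 2, where it is 0.0952. The unpaired two-sided p is 2 times the smaller one-sided p, and it is this doubling that sets the limit for 5 against 2. With these tests, the comparisons with healthy skin and the paired comparison cannot reach 0.05 for a list level.

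The fits were tested on simulated reads drawn from the means, totals and spread of the real genes, with 200 genes changed. The changed genes were drawn from those with a mean of at least 50 scaled reads, so recovery at lower levels was not measured. Of genes changed by 1, 2 and 3 on the log2 scale, 13.4, 61.2 and 78.8% were recovered for before against healthy, 44.8, 86.6 and 90.9% for after against before, and 13.4, 76.1 and 80.3% for after against healthy. False calls made up 11.3, 5.13 and 3.42% of the calls in this order. A simulated change of 1 was missed in most genes in each of the 3 comparisons. The simulated genes were drawn independently, with no patient effect and no library rich in ribosomal RNA. These shares may therefore differ from those in the real libraries.

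Alternatives planned before the data were examined were other offsets, no filter and a stricter filter, median-of-ratios size factors, quantile normalization, other variance models, array weights, a looser threshold, fits on 2 groups, the patient as a block and leaving out each library. Added after the data were seen were an offset of 0.1, recovered reads scaled to the median depth plus 1, voom on recovered reads, size factors for the list, direction and named-gene results, and size factors without after replicate 4. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.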

Results

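Lesional skin of 5 patients with granuloma annulare was profiled by RNA sequencing before and after 6 months of tofacitinib, beside 2 libraries of healthy skin. Recovered library totals were 20353747 to 41859977 reads before treatment, 13662465 to 32079507 after treatment and 18250825 to 22358499 in healthy skin. Levels are given as mean RPKM over the gene span ± SD, with n = 5 before, n = 5 after and n = 2 healthy libraries, and differences as log2 of RPKM plus 1. After replicate 4 stood apart in its ribosomal RNA, with 26215 RPKM for 28S rRNA against 590 to 5137 in the other 11 libraries, and 48.2% of its RPKM sum lay in rRNA genes, against 5.64 to 20.2% in the others. Its size factor was 0.70, against 0.90 to 1.14 in the others.

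The first comparison asked which genes differ between untreated granuloma annulare and healthy skin. Untreated lesions held high levels of macrophage and interferon-induced transcripts. LYZ, the lysozyme of myeloid cells, reached 725 ± 188 RPKM (n = 5) against 5.36 ± 5.23 in healthy skin (n = 2), a 135-fold ratio of means. CXCL9, a chemokine induced by interferon gamma, was at 159 ± 64.9 against 0.763 ± 0.595 RPKM, and the lysosomal macrophage marker CD68 at 226 ± 44.1 against 3.06 ± 1.63. Transcripts of the immediate early genes FOS and FOSB, the cornified envelope gene LCE2C and the keratin genes KRT1 and KRT77 were lower in the lesions. Of the 16857 genes tested, 6025 changed (limma, adjusted p under 0.05), of which 3919 were higher and 2106 lower before treatment. A log2 difference of at least 1 was reached by 727 of the higher and 599 of the lower genes. The values of the groups did not overlap in 60.8% of the tested genes, where chance gives 9.52%.

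The 8 genes with the largest increase were LYZ (7.09 on the log2 scale, SE 1.46, adjusted p = 0.0053), SPP1, CXCL9, CD68, C1QA, FN1, CXCL10 and MPEG1. SPP1 encodes osteopontin, C1QA a chain of complement C1q made by macrophages, FN1 fibronectin and MPEG1 the macrophage pore-forming protein perforin-2. Their means were 49.3 to 208 times those of healthy skin, and their adjusted p-values lay between 0.0013 and 0.0099. CXCL9 and CXCL10 lie side by side on chromosome 4 (GRCh38, 76001275 to 76007509 and 76021118 to 76023497). IFNG on chromosome 12 (68154768 to 68159740), the gene for interferon gamma, was at 0.306 ± 0.062 RPKM (31 to 50 recovered reads per library) before treatment and listed at 0 in both healthy libraries, which makes it at least 20.6-fold higher against a floor of 3 reads over the healthy group (log2 difference 0.38, adjusted p = 0.0007). Of the panel, JAK2 and JAK3 rose 4.14-fold and 28.2-fold in mean RPKM (adjusted p = 0.0033 and 0.0056), whereas JAK1 and TYK2 did not pass (adjusted p = 0.16 and 0.38). The cytokine genes TNF, OSM, IL15 and IL21 passed at low levels (0.0878 to 3.13 RPKM) and IL6 did not (adjusted p = 0.069). GBP5, IRF1, IDO1, CD3E, CD163, CHIT1, MMP9 and COL1A1 also rose, and the values of ELN and SOCS3 did not pass (adjusted p = 0.13 and 0.18).

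The 8 genes with the largest decrease were FOS, FOSB, DUSP1, EGR1, FGFBP1, LCE2C, KRT77 and MFSD2A. FOS on chromosome 14 (75278828 to 75282230) was at 6.81 ± 3.22 RPKM before treatment against 584 ± 298 in healthy skin, and FOSB at 0.219 ± 0.080 against 49.1 ± 42. DUSP1, a phosphatase induced by stress, and the immediate early factor EGR1 were 19.4-fold and 17.3-fold lower. The adjusted p-values of the 8 genes were 4.1e-05 to 0.012.

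By gene list, 27 of 39 lists were called in this comparison, 21 higher and 6 lower. All 22 macrophage genes rose (median log2 difference 3.81, camera adjusted p = 9.8e-08; adjusted p = 0.47 with an estimated correlation), and also 22 adjusted over the list alone. Of the 27 interferon gamma response genes 22 rose and 5 did not pass, with 25 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.8e-09; adjusted p = 0.47 with an estimated correlation). GBP1, a guanylate-binding protein, was at 14.4 ± 3.77 against 0.708 ± 0.088 RPKM. All 20 Th1 and cytotoxic genes rose, among them GZMB, the protease granzyme B (3.68 ± 0.894 against 0.029 ± 0.017 RPKM), and NKG7; 20 rose adjusted over the list alone (camera adjusted p = 5.6e-08; adjusted p = 0.47 with an estimated correlation). Of 22 type I interferon response genes 20 rose, and 22 adjusted over the list alone, and of 19 T cell genes 18 rose, with 18 adjusted over the list alone (camera adjusted p = 5.3e-08 and 1e-05; adjusted p = 0.47 and 0.51 with an estimated correlation). All 12 genes of MHC class II presentation rose, and 14 of 16 complement genes, the same counts as adjusted over the list alone (camera adjusted p = 6.8e-05 and 5.3e-07; adjusted p = 0.47 and 0.45 with an estimated correlation). Of the 25 genes of granuloma and lysosomal macrophages 18 rose and 7 did not pass, with 18 adjusted over the list alone; CYP27B1, which makes active vitamin D, was at 1.81 ± 0.37 against 0.143 ± 0.0425 RPKM (camera adjusted p = 1.3e-05; adjusted p = 0.47 with an estimated correlation).

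Matrix genes were higher as well, and whether the lesional biopsies held more dermis than the healthy ones was not tested. Of 24 fibrillar collagen and matrix genes 19 rose and none fell, with 21 adjusted over the list alone (camera adjusted p = 5e-07; adjusted p = 0.45 with an estimated correlation), of 16 dermal fibroblast genes 13 rose, with 14 adjusted over the list alone (camera adjusted p = 2e-05; adjusted p = 0.45 with an estimated correlation), and of 15 elastic fibre genes 11 rose, with 12 adjusted over the list alone (camera adjusted p = 0.0001; adjusted p = 0.45 with an estimated correlation). COL6A3, a chain of type VI collagen, was at 14.3 ± 2.99 against 0.503 ± 0.229 RPKM and the proteoglycan gene DCN at 55.3 ± 26.6 against 3.95 ± 0.28 RPKM. Of 21 matrix proteases and inhibitors 15 rose, with 17 adjusted over the list alone; MMP2, a gelatinase, was at 42.7 ± 17.7 against 1.41 ± 0.569 RPKM (camera adjusted p = 2.3e-06; adjusted p = 0.45 with an estimated correlation). In contrast, 17 of 19 differentiated keratinocyte genes fell, with 17 adjusted over the list alone (median log2 difference -1.88, camera adjusted p = 5.4e-11; adjusted p = 0.45 with an estimated correlation), including KRT1 at 898 ± 191 against 4362 ± 50.1 RPKM and the corneodesmosin gene CDSN. Of 22 immediate early and heat shock genes 16 fell, with 16 adjusted over the list alone (camera adjusted p = 3.5e-09; adjusted p = 0.45 with an estimated correlation). Of 30 cytosolic ribosomal protein genes 27 fell, with 29 adjusted over the list alone (median -1.07, camera adjusted p = 3.1e-13; adjusted p = 0.45 with an estimated correlation). Exact permutation of the list levels gave p = 0.0952, the smallest possible with 5 against 2 libraries when the one-sided p is doubled, for each list named in this and the preceding paragraph.

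The count of changed genes rested on both healthy libraries: without healthy replicate 1 it was 1661 and without healthy replicate 2 it was 2322. The scaling set the balance of directions, with 3708 higher and 3976 lower genes with size factors and 3005 higher and 4382 lower with quantile normalization, against 3919 and 2106 on the deposited values.

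**Figure D1:**
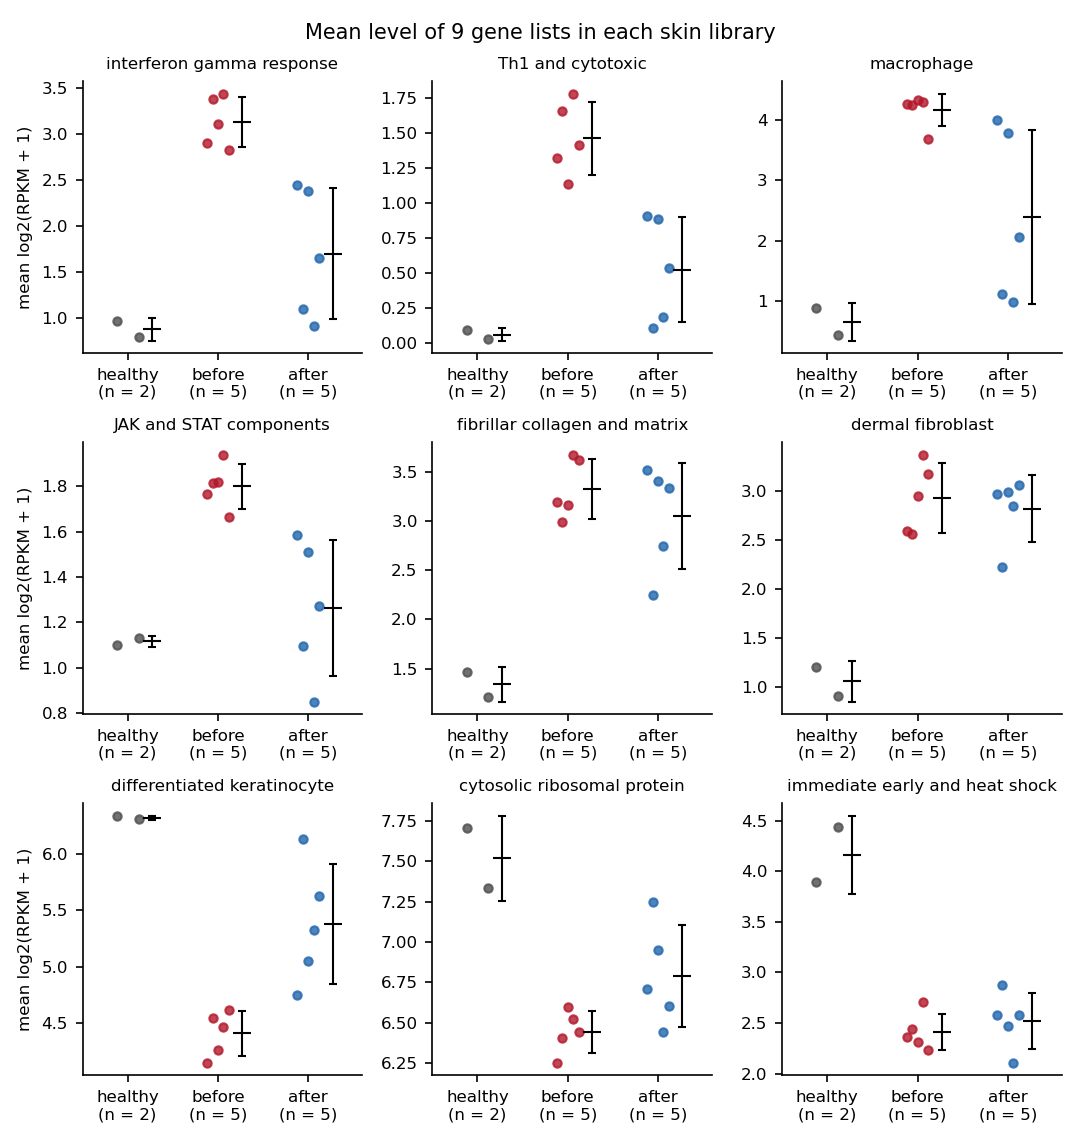
Mean of log2(RPKM + 1) over the members of 9 gene lists in each library (points; healthy n = 2, before n = 5, after n = 5); bars give the group mean ± SD, and each vertical axis has its own range. The interferon gamma response list lay at 3.14 ± 0.28 before, 1.70 ± 0.71 after and 0.88 ± 0.13 in healthy skin, while the dermal fibroblast list lay at 2.93 ± 0.36, 2.82 ± 0.34 and 1.05 ± 0.21.

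The second comparison asked what changed in lesional skin over the 6 months of tofacitinib. The genes that fell included IFNG, the interferon-induced chemokine genes CXCL10 and CXCL11 and the cytotoxic cell gene GZMB. IFNG went from 0.306 ± 0.062 RPKM before to 0.048 ± 0.042 after treatment (n = 5 each; 0 to 16 recovered reads after, log2 difference -0.32, SE 0.035, adjusted p = 0.0068), 6.38-fold lower and lower in 5 of 5 pairs. CXCL10 fell from 46.1 ± 10.5 to 5.30 ± 4.86 RPKM (8.70-fold, adjusted p = 0.038), granzyme B (GZMB) from 3.68 ± 0.894 to 0.477 ± 0.337 (adjusted p = 0.0068) and IDO1, a tryptophan-degrading enzyme induced by interferon gamma, from 1.62 ± 0.467 to 0.210 ± 0.164 (adjusted p = 0.0068). Each of these was lower in 5 of 5 pairs. In total 33 genes changed (limma, adjusted p under 0.05), 32 lower and 1 higher, and 10 of them by at least 1 on the log2 scale, all lower. With the patient as a fixed block limma called 0 genes, with a smallest adjusted p of 0.0779 and 4597 genes at an unadjusted p under 0.05. That fit used the 10 patient libraries only. Without the block, the same 10 libraries gave 8 called genes and 3896 at an unadjusted p under 0.05, against 33 and 4204 over all 12 libraries. With the block, the 4 genes above had adjusted p-values of 0.0779 to 0.090. Of all tested genes 26.7% moved the same way in all 5 pairs, where chance gives 6.25%.

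The count of 33 depended on single libraries and on the scaling. It was 2611 without after replicate 1, 366 without after replicate 3, 5, 6 and 9 without after replicates 4, 5 and 2, 8 without either healthy replicate or before replicate 4, and 16, 17 and 13 without before replicates 1, 2 and 3. With size factors it was 292 (50 higher, 242 lower), with quantile normalization 492 (111 higher, 381 lower), and with both after replicate 4 left out and size factors it was 5.

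The 8 genes with the largest fall under the naming rule were CXCL10, GBP1, CXCL11, CCL2, CCL8, SLAMF7, GZMB and PARP9, each lower in 5 of 5 pairs. CXCL11 is a further ligand of the receptor CXCR3, CCL2 and CCL8 are monocyte chemokines on chromosome 17 (34255285 to 34257203 and 34319435 to 34321402), SLAMF7 is a receptor of cytotoxic and plasma cells, and PARP9 is an interferon-induced ADP-ribosyltransferase. Their log2 differences were -3.30 to -1.13, with adjusted p-values of 0.0068 to 0.044 that became 0.0779 to 0.090 with the patient as a block. CCL2 went from 17.0 ± 4.43 to 4.10 ± 1.90 RPKM, beside 3.84 ± 0.84 in healthy skin. CYP27B1 also fell (1.81 ± 0.37 to 0.375 ± 0.306 RPKM, adjusted p = 0.029, and 0.0779 with the patient as a block). The gene that rose was HOXC11, a homeobox gene named here after its values were seen, from 0.117 ± 0.012 to 0.291 ± 0.062 RPKM, which is 10 to 24 reads per library before and 19 to 41 after. No higher gene met the naming rule. The 4 filled by smallest p, which did not pass, were the epidermal genes KLK11, LCE1C, LCE1A and SBSN, each higher in 5 of 5 pairs by 2.66-fold to 3.69-fold (adjusted p = 0.068 each). In the panel, SOCS3, a feedback inhibitor of JAK signalling, was at 10.1 ± 4.02 RPKM before and 2.62 ± 1.80 after treatment. It was lower in 5 of 5 pairs and did not pass (adjusted p = 0.075). CXCL9, GBP5, IRF1, OSM, IL21, IL6, JAK2, JAK3, CD3E, CD68 and CD163 were also lower in 5 of 5 pairs, and IL15, TNF and CHIT1 in 4 of 5. None of these passed, with adjusted p-values between 0.063 and 0.12. MMP9, JAK1, TYK2, COL1A1 and ELN had adjusted p-values of 0.20 to 0.81; COL1A1 was at 91.8 ± 64.8 before and 122 ± 71.9 RPKM after treatment.

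By gene list, 23 of 39 were called, 16 lower and 7 higher. Adjusted within this comparison 22 were called, a number that 32 of 100 splits of the 10 patient libraries reached, the real one included. Of the interferon gamma response genes 5 of 27 fell, and 24 adjusted over the list alone (median -1.25, camera adjusted p = 1.8e-15; adjusted p = 0.45 with an estimated correlation). Of the 20 Th1 and cytotoxic genes 2 fell, and 20 adjusted over the list alone (camera adjusted p = 1e-13; adjusted p = 0.45 with an estimated correlation). The type I interferon response had 1 of 22 genes lower, RSAD2, and 19 adjusted over the list alone (camera adjusted p = 2.9e-12; adjusted p = 0.45 with an estimated correlation). None of 22 macrophage genes passed over all genes, and 22 were lower adjusted over the list alone (median -1.91, camera adjusted p = 6.8e-09; adjusted p = 0.47 with an estimated correlation); C1QB was at 31.7 ± 11.4 before and 7.95 ± 7.78 RPKM after treatment. For T cells 0 of 19 passed and 18 were lower adjusted over the list alone, and for JAK and STAT components 0 of 26 passed and 20 were lower adjusted over the list alone (camera adjusted p = 6.1e-08 and 1.9e-08; adjusted p = 0.47 and 0.45 with an estimated correlation). TNF and NF-kB targets had 1 of 22 lower and 16 adjusted over the list alone, granuloma and lysosomal macrophages 1 of 25 and 19, and cytokines signalling through JAK 1 of 15 and 8, with 1 higher (camera adjusted p = 9.1e-08, 1.5e-07 and 0.0027; adjusted p = 0.45, 0.47 and 0.45 with an estimated correlation). The call of the cytokine list was lost with the stricter filter (adjusted p = 0.576). MHC class II presentation, complement, dendritic and Langerhans cells and matrix proteases had 0 genes past the threshold over all genes and 12 of 12, 13 of 16, 11 of 16 and 12 of 21 lower adjusted over the list alone (camera adjusted p = 3.9e-06, 1.9e-06, 2.6e-05 and 3e-05; adjusted p = 0.47, 0.45, 0.45 and 0.47 with an estimated correlation). Higher lists included differentiated keratinocytes, with 0 of 19 genes passing over all genes and 17 higher adjusted over the list alone (median 0.88, camera adjusted p = 1.9e-12; adjusted p = 0.45 with an estimated correlation), basal keratinocytes (0 of 12 and 1, camera adjusted p = 0.00012; adjusted p = 0.47 with an estimated correlation) and ribosomal proteins (0 of 30 and 0 adjusted over the list alone, although 30 of 30 differences were positive; camera adjusted p = 9.1e-08; adjusted p = 0.47 with an estimated correlation). The other higher lists were eccrine sweat gland, melanocyte, nerve and Schwann cell, and skeletal muscle (camera adjusted p = 0.0049, 0.025, 0.025 and 0.048; adjusted p = 0.51, 0.66, 0.47 and 0.45 with an estimated correlation). None of their genes passed over all genes, and 1 of 13, 0 of 10, 3 of 11 (with 1 lower) and 0 of 7 were higher adjusted over the list alone. Their levels were higher in 4, 4, 3 and 5 of 5 pairs, and their calls were lost in 2, 8, 3 and 11 of 18 other settings, with highest adjusted p-values of 0.223, 0.158, 0.0884 and 0.461. All 4 calls were lost without after replicate 4, that of melanocytes also without before replicate 3 or 4 or after replicate 2, and that of skeletal muscle without before replicate 1, 4 or 5 or after replicate 3.

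In the unpaired exact permutation of the 10 patient libraries, the levels of 9 of the 39 lists passed between after and before (p = 0.00794, the smallest possible, adjusted p = 0.0344). This test ignores that the libraries are paired by patient. The 8 lower ones were the interferon gamma response (by 1.43 ± 0.93, SD of the paired change), Th1 and cytotoxic, granuloma and lysosomal macrophage, JAK and STAT components, TNF and NF-kB targets, MHC class II, dendritic and Langerhans cell, and complement. The higher one was differentiated keratinocytes (0.97 ± 0.38). All 9 moved the same way in 5 of 5 pairs, and the paired exact permutation p was 0.0625 for each, the smallest it can give (adjusted p = 0.135). None of the 9 therefore passed with the pairing kept, a test that could not have passed any list. The macrophage list (change -1.78 ± 1.41, lower in 5 of 5 pairs) had an exact adjusted p of 0.0663. The size of the change differed between pairs, from -3.31 to -0.27 for the macrophage list, from -2.52 to -0.45 for the interferon gamma response, from -3.13 to -0.09 for MHC class II and from -1.22 to 0.03 for T cells. The same 2 of the 5 pairs, those of replicates 1 and 3, had the smallest changes on each of these 4 lists. These are also the pairs whose after libraries, when left out, raised the count of called genes. The fibrillar collagen and matrix, dermal fibroblast, elastic fibre, and immediate early and heat shock lists were not called. The fibrillar collagen and matrix list changed by -0.28 ± 0.56 (lower in 3 of 5 pairs, exact p = 0.37), the dermal fibroblast list by -0.11 ± 0.35 (exact p = 0.64), the elastic fibre list by 0.06 ± 0.24 (exact p = 0.68) and the immediate early and heat shock list by 0.11 ± 0.41 (exact p = 0.45). No member of these 4 lists passed in limma, over all genes or adjusted over the list alone. The median of the elastic fibre list was -0.01, of the other sign than its mean. A p above the threshold does not show that these levels were equal.

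Of the 6025 genes that differed before treatment from healthy skin, 5560 (92.3%, exact 95% interval 91.6 to 92.9%, which covers counting error only and takes genes as independent) had a difference after against before of the opposite sign. Both differences use the same before libraries, which by itself favours opposite signs. Simulated data with no change in any group gave a median of 74.8% and at most 99.1%, and simulated data with the disease difference kept and no treatment change gave a median of 61.9% and at most 91.5%, so 0 of the latter 100 reached the observed share. The simulated libraries carried no pairing of patients, and their spread was pooled over the groups. Simulated shares may therefore differ from those that paired libraries of unequal spread would give. The covariance of the differences was -0.163, against -0.012 in the simulation with the disease difference kept, a difference of -0.151. With the patients split so that separate people gave the disease and the treatment difference, the median share was 89.5% and the highest 93.5%. Of the 20 values 1 could not be had, since no gene was called, and the lowest was 0%, from a split with 1 called gene. The next lowest was 69.1%, from a split with 4781 called genes. In these splits the disease and the treatment difference share no before library. The simulated shares, where they do share them, are therefore no reference for the split values.

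The third comparison asked which differences from healthy skin were present after 6 months. Extracellular matrix and fibroblast transcripts were higher and immediate early transcripts lower than in healthy skin. The levels of the blood endothelial, lymphatic endothelial and mast cell lists were also higher (by 0.45, 0.83 and 0.89). That of the differentiated keratinocyte list was lower (-0.94). The pericyte and smooth muscle list, higher by 0.34, was not called. Whether the patient biopsies held more dermis than the healthy ones was not tested. MFAP4, a protein of elastic microfibrils, was at 78.5 ± 19.8 RPKM after treatment (n = 5) against 4.45 ± 2.11 in healthy skin (n = 2), 17.7-fold higher (adjusted p = 0.0016), and COL1A1, a chain of type I collagen, at 122 ± 71.9 against 9.37 ± 2.72 (13.0-fold, adjusted p = 0.029). FOS was at 14.3 ± 17.6 against 584 ± 298 RPKM (adjusted p = 0.0023). In limma 1275 genes changed, 615 higher and 660 lower, of which 125 and 136 reached a log2 difference of 1. Without healthy replicate 1 the count was 165 and without healthy replicate 2 it was 411. Leaving out after replicates 1, 3 and 5 gave 803, 716 and 777, and leaving out after replicates 2 and 4 gave 2904 and 2243. With size factors 1332 genes were higher and 2340 lower, and with quantile normalization 854 and 2275. The main fit shares its variance over all groups, although the after libraries varied more on some lists than the before libraries. The SD of the macrophage list level was 1.44 after and 0.27 before treatment, and that of the interferon gamma response 0.71 and 0.28. Fitted on the after and healthy libraries alone, limma called 235 genes (146 higher, 89 lower).

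The 8 largest increases were MFAP4, MMP2, CCL21, LUM, RNASE1, COL3A1, C1S and COL1A1 (log2 3.88 to 3.30, 13.0-fold to 29.8-fold, adjusted p = 0.00104 to 0.0315). CCL21 is a chemokine of lymphatic endothelium, LUM the collagen-binding proteoglycan lumican, RNASE1 a ribonuclease of endothelial cells and C1S a protease of the complement system. Among the 8 largest decreases were FOS, FOSB, EGR1, DUSP1, MYC, ZFP36 and MT1X (log2 -5.75 to -2.80, adjusted p = 8.2e-05 to 0.0023), of which ZFP36 encodes an mRNA-decay factor and MT1X a metallothionein. In the panel, COL1A1 and ELN were higher (ELN 2.75 ± 1.13 against 0.296 ± 0.098 RPKM, adjusted p = 0.046) and SOCS3 lower (adjusted p = 0.020). The other panel genes did not pass. Among them, CXCL9 was at 34.5 ± 37.3 against 0.763 ± 0.595 RPKM (adjusted p = 0.095), CXCL10 at 5.30 ± 4.86 against 0.492 ± 0.50 (adjusted p = 0.14) and CD68 at 87.4 ± 99.1 against 3.06 ± 1.63 (adjusted p = 0.087). IFNG was at 0.048 ± 0.042 RPKM after treatment and listed at 0 in both healthy libraries (adjusted p = 0.35).

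Of 39 lists 23 were called, 16 higher and 7 lower. Of the fibrillar collagen and matrix genes 14 of 24 rose, and 18 adjusted over the list alone (median 1.55, camera adjusted p = 5.9e-10; adjusted p = 0.45 with an estimated correlation), of dermal fibroblast genes 9 of 16, and 15 adjusted over the list alone (camera adjusted p = 8.1e-09; adjusted p = 0.45 with an estimated correlation), and of elastic fibre genes 9 of 15, and 12 adjusted over the list alone (camera adjusted p = 4.7e-08; adjusted p = 0.45 with an estimated correlation). Macrophage genes had 0 of 22 past the threshold, over all genes and adjusted over the list alone, with a median of 1.79 (camera adjusted p = 9.7e-05, and adjusted p = 0.60 with an estimated correlation). The after libraries differed widely on this list. After replicates 1 and 3 had levels of 4.00 and 3.79, within the 3.69 to 4.34 of the before libraries. The other after libraries lay at 0.98 to 2.06, and the healthy ones at 0.87 and 0.43. Genes that did not pass were therefore not shown to be at healthy levels. For the interferon gamma response 1 of 27 rose, SERPING1, and 1 adjusted over the list alone (median 0.73, camera adjusted p = 0.0022; adjusted p = 0.67 with an estimated correlation). For Th1 and cytotoxic genes 0 of 20 passed either way (camera adjusted p = 0.014, and uncalled with an offset of 10; adjusted p = 0.69 with an estimated correlation). Of 22 immediate early and heat shock genes 12 fell, and 14 adjusted over the list alone (camera adjusted p = 4.7e-12; adjusted p = 0.45 with an estimated correlation). Differentiated keratinocyte genes had 4 of 19 lower, and 10 adjusted over the list alone, and ribosomal protein genes 3 of 30, and 20 adjusted over the list alone (camera adjusted p = 2.2e-06 and 1.3e-11; adjusted p = 0.47 and 0.45 with an estimated correlation). Both calls were lost with quantile normalization, with adjusted p = 0.068 and 0.10. JAK and STAT components were not called (camera adjusted p = 0.068; adjusted p = 0.72 with an estimated correlation), but were called higher with quantile normalization, with size factors, without after replicate 2 and without after replicate 4, with or without size factors.

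**Figure D2:**
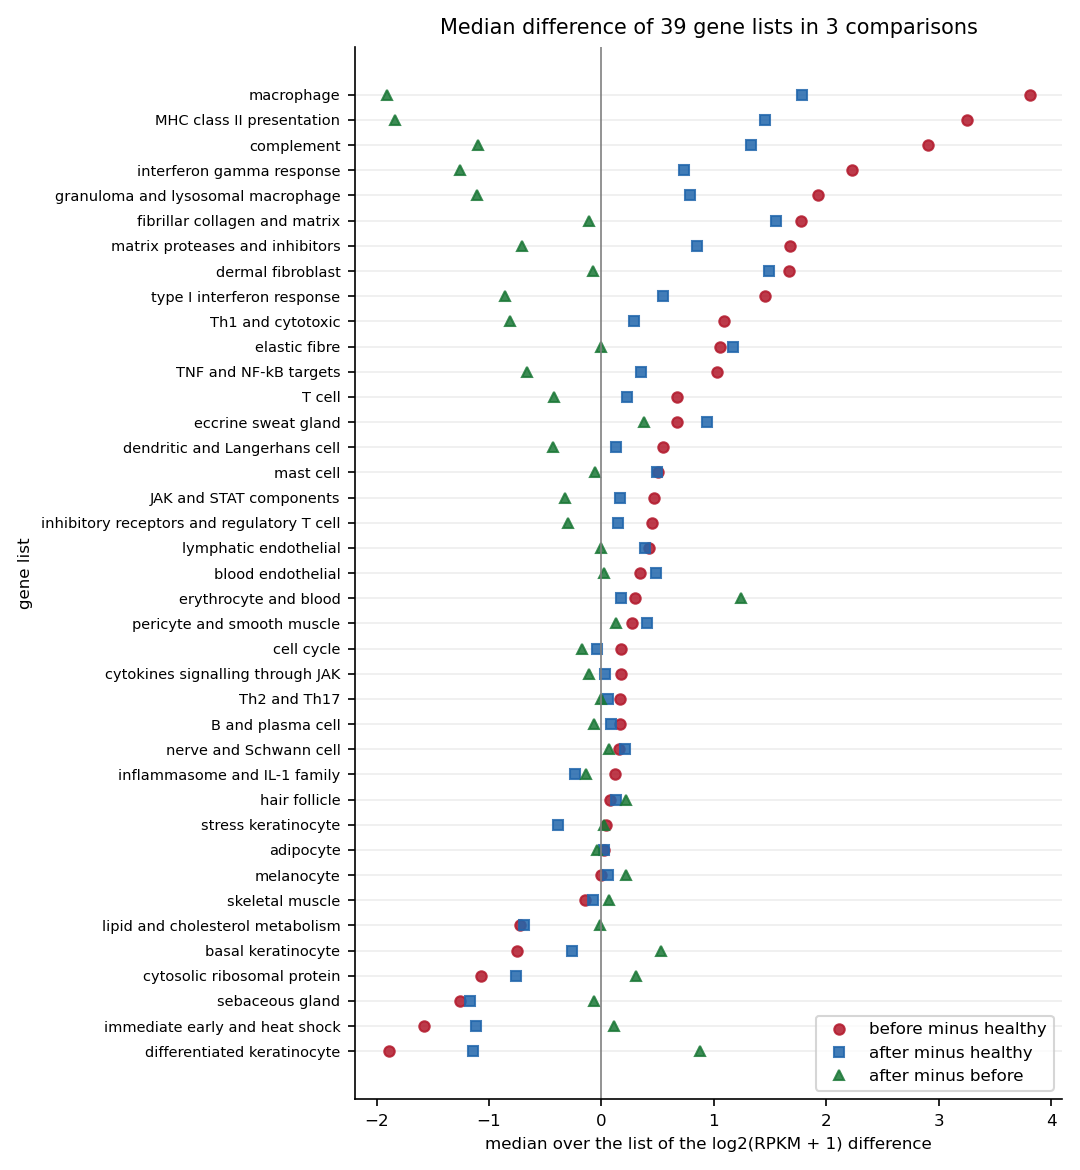
Median over the members of each of 39 gene lists of the difference in log2(RPKM + 1), for before minus healthy (circles), after minus healthy (squares) and after minus before (triangles); lists are ordered by the first. The macrophage list had medians of 3.81, 1.79 and -1.91, and the fibrillar collagen and matrix list 1.77, 1.55 and -0.11.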

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

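All tests of technical explanations in this part were chosen only after the result was seen, apart from the test of gene span and the counts over other splits of the libraries. In 206 groups of 5 libraries, the gap of the highest or lowest library to its nearest neighbour, divided by the range of the group, was compared with 0.71, which chance exceeds in about 1 of 20 groups. It was exceeded 11 times, where 10.3 are expected by chance, so the number of flags does not stand out. The flags are not independent, since several come from the same library or patient.

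In the after group, 1 library had the lowest median RPKM (0.175 against 0.265 to 0.290, ratio 0.778). The highest 28S rRNA of the after group was 26215 RPKM against 687 to 2963 (ratio 0.911), and the highest share of the RPKM sum in rRNA genes was 48.2% against 5.64 to 13.7% (ratio 0.811). The lowest macrophage list level before treatment was 3.69 against 4.24 to 4.34 (ratio 0.853). The lowest dermal fibroblast level after treatment was 2.22 against 2.85 to 3.07 (ratio 0.737), and the highest adipocyte level after treatment was 0.978 against 0.421 to 0.543 (ratio 0.782). The highest sebaceous gland level was 1.73 against 0.361 to 0.582 before (ratio 0.839) and 1.65 against 0.305 to 0.415 after treatment (ratio 0.918). The highest hair follicle level was 1.10 against 0.124 to 0.244 before (ratio 0.877) and 1.84 against 0.189 to 0.344 after treatment (ratio 0.906). The lowest level of MFAP4 after treatment was 5.51 against 6.33 to 6.59 on the log2 scale (ratio 0.761). The flags on median RPKM and rRNA came from after replicate 4. Those on the dermal fibroblast, adipocyte, sebaceous gland and hair follicle lists all came from replicate 2. After replicate 2 also had the lowest collagen list level of the after group (2.24). Its basal keratinocyte level was 4.15, against 3.68 and 3.63 in healthy skin. Why replicate 2 differed was not tested.

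Lists of interferon gamma response and macrophage genes were called lower after treatment than before, with 5 of 27 and 0 of 22 genes past the threshold over all genes (adjusted p = 0.45 and 0.47 with an estimated correlation). The library rich in rRNA and the library scaling were argued against by the median of the interferon gamma response list, which was -1.03 without after replicate 4 and with size factors (macrophage list -1.54), against -1.25 and -1.91 on the deposited values. The dermal fibroblast list, a measure of dermis, changed by 1.67 ± 1.09 (SD over pairs) more than the macrophage list, in 5 of 5 pairs. In replicate 2 this was fixed in advance, since macrophages fell from 4.24 to 1.12 and the fibroblast and collagen lists started at 2.56 and 2.98. In replicate 4 it was nearly so (4.29 to 0.98, fibroblasts 3.37 before). In replicates 1, 3 and 5 fibroblasts went from 2.59, 2.95 and 3.17 to 2.97, 3.00 and 3.07. This argues against less dermis after treatment in those pairs only. The signed change of the collagen list also lay above that of the macrophage list in 5 of 5 pairs. The endothelial and mast cell lists cannot decide whether dermis was lost. In several pairs the macrophage list fell by more than their whole level before treatment, and a level cannot be negative. A change over 6 months that would occur without the drug stays open, because 0 patients were followed without it. The decrease may therefore follow the drug or the course of the disease, and the design cannot separate them. In the pairs of replicates 2 and 4, less dermis stays open as well.

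From the 126 splits of the 10 patient libraries into 5 and 5, 100 were drawn. Only the real one called as many genes in limma (33, highest other 4). The libraries are paired, and only 13 of the 100 splits part all 5 pairs. This share therefore does not exclude chance for the count of genes. The 16 splits that part all 5 pairs, as the real one does, are too few for a share under 0.05 (real 33, highest other 1), and with the patient as a fixed replicate block limma called 0 genes (4597 at an unadjusted p under 0.05). For the lists chance cannot be excluded: 32 of the 100 splits called at least as many lists with camera as the real one (22 of 39 when adjusted within this comparison, highest other 28, median of the others 19), and so did 7 of the 16 splits that part all pairs. Camera with a preset correlation thus makes many list calls in splits that do not follow the treatment.

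Immediate early genes were lower in both patient groups than in healthy skin. Less epidermis in the lesions was argued against, since the immediate early list closed 4.58% ± 26.2 (SD over pairs) of its difference to healthy skin, with an upper limit of 28.0% at 2 standard errors, while the differentiated keratinocyte list closed 52.2% ± 23.8. The pair of after replicate 4, the library rich in rRNA, lowered this mean for the immediate early list. In that pair the list fell from 2.70 to 2.11, while it rose in the other 4 pairs. Handling of the biopsies or their site stays open. The highest patient library lay at 2.87 and the lower healthy library at 3.89 on the list level, so 0 of the 10 patient libraries reached healthy skin, and the labels give no handling within a group. A difference in handling and a property of lesional skin cannot be told apart here.

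Ribosomal protein genes were lower in lesional skin before treatment than in healthy skin. Their short span was argued against by 125 genes matched on span and mean level, whose median difference was 0.0781, against -1.07 for the list. The lowest median of 10000 random matched lists was -0.98. The library scaling as the whole cause was argued against by a median of -0.61 with quantile normalization and -1.32 with size factors. A difference in cell types or in RNA handling was not tested and stays open.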

How the results depend on the processing

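The offset of 0.1, scaled reads plus 1, voom, size factors for lists, directions and named genes, and size factors without after replicate 4 were chosen only after the data were seen. Where no reason is given for a change, the cause was not tested. For before against healthy the count of 6025 became 9047 with array weights and lay between 5424 and 7799 in the other settings with all libraries. Leaving out 1 library gave 1661 to 6914, and without a healthy replicate the lone healthy library is assumed to vary like the other groups. For after against before the count of 33 became 75 with an offset of 10, 10 with an offset of 0.1, 20 without a filter, 361 with the stricter filter, 292 with size factors, 492 with quantile normalization, 6 without a trend, 16 with array weights, 1414 at an adjusted p under 0.10, 8 in the fit on 2 groups and 5 with voom. It was 0 with scaled reads plus 1 in limma (4290 at an unadjusted p under 0.05). Without after replicate 4 and with size factors it was 5. As a random replicate block the patient gave 1614, and as a fixed block 0 (4597 at an unadjusted p under 0.05), also 0 without any 1 of the 5 pairs. Leaving out 1 library without the block gave 5 to 2611. For after against healthy the count of 1275 became 3672 with size factors, 3129 with quantile normalization, 5676 with array weights, 2688 at an adjusted p under 0.10, 1946 with an offset of 0.1, 3181 with scaled reads plus 1 (2504 higher, 677 lower), 2120 with voom (1403 higher, 717 lower) and 235 in the fit on 2 groups, and leaving out 1 library gave 165 to 2904. Scaled reads plus 1 moved the median of all genes from 0.02 to 0.26 for before against healthy, from -0.01 to -0.11 for after against before and from 0.01 to 0.15 for after against healthy.

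Of 117 list tests 73 were called, and 0 with an estimated correlation, where camera takes members as dependent. Fry called 52, the fixed patient block 75, and the other settings 67 to 75. With the block, hair follicle (higher, adjusted p = 0.013) and sebaceous gland (lower, adjusted p = 0.028) were called in addition (adjusted p = 0.547 and 0.615 with the block and an estimated correlation), and no called list was lost. The sebaceous gland list was called lower in camera before and after treatment than in healthy skin (adjusted p = 0.0021 and 8e-05; adjusted p = 0.59 and 0.47 with an estimated correlation, and uncalled in fry), and turned to higher and uncalled without healthy replicate 1 (adjusted p = 0.83 and 0.94). The share of opposite directions, 92.3%, was 88.9% with quantile normalization, 88.2% with size factors, 90.0% at an adjusted p under 0.10, 89.6% with scaled reads plus 1, 89.5% with the patients split and 87.6 to 93.8% without 1 library. Of the genes named by size of change 40 passed, 36 with an offset of 10, 32 with the block and 32 with scaled reads plus 1, and 26 (without healthy replicate 2) to 38 without 1 library.

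Of the differences of named genes under the alternatives, 5070 kept their direction and side of the threshold, 316 passed in addition, 373 no longer passed and 15 changed sign. TYK2 after against before was -0.013 without after replicate 3, and at most 0.178 without another library. OSM after against healthy was 0.000995 without after replicate 2, 4 or 5 and 0.00674 without healthy replicate 2, and -0.0161 without healthy replicate 1. IL6 after against healthy was -0.0733 with quantile normalization, -0.0201 with size factors, -1.14 with scaled reads plus 1, -0.0759 without after replicate 1, -0.00288 without after replicate 3 and -0.00631 without healthy replicate 2, and at most 0.0453, without after replicate 2. Without healthy replicate 1, FA2H was 0.024 before and 0.0125 after treatment against healthy, AWAT1 0.0117 before and CIDEA 0.0766 after treatment. Without healthy replicate 2 these values were -1.56, -1.57, -3.48 and -2.03. With 2 healthy libraries and recovered totals from 13662465 reads, genes near the filter are measured with few reads, and their differences are the least certain.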

Other observations

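The comparison of the interferon gamma response and macrophage lists at the end of this part was chosen only after the result was seen. Cell cycle genes were called lower after treatment than before, with 0 of 22 past the threshold over all genes and 11 lower adjusted over the list alone (camera adjusted p = 7.8e-06; adjusted p = 0.47 with an estimated correlation). MKI67, a marker of dividing cells, was at 1.97 ± 0.523 RPKM before and 1.05 ± 0.282 after treatment, lower in 5 of 5 pairs, and did not pass (adjusted p = 0.073). Inhibitory receptor and regulatory T cell genes were higher before treatment than in healthy skin in 9 of 14 cases, and 10 with 1 lower adjusted over the list alone (camera adjusted p = 0.0033; adjusted p = 0.50 with an estimated correlation). The anti-inflammatory cytokine gene IL10 was at 0.477 ± 0.080 against 0.011 ± 0.016 RPKM (adjusted p = 0.0022). Of 16 dendritic and Langerhans cell genes 9 were higher and 1 lower before treatment than in healthy skin, and 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.022, lost with the stricter filter; adjusted p = 0.59 with an estimated correlation). The lower one was CD207, the langerin gene of epidermal Langerhans cells (5.95 ± 1.15 against 21.1 ± 0.769 RPKM, adjusted p = 0.0047), while the chemokine gene CCL19 was at 67.0 ± 33.2 against 2.13 ± 1.47 RPKM (adjusted p = 0.0047).

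Mast cell genes were higher in both patient groups than in healthy skin, 8 of 10 before treatment (9 adjusted over the list alone) and 4 of 10 after (9 adjusted over the list alone; camera adjusted p = 0.00095 and 3.3e-05; adjusted p = 0.45 for both with an estimated correlation). CMA1, the mast cell chymase gene, was at 2.06 ± 0.731 RPKM before, 1.09 ± 0.152 after and 0.115 ± 0.076 in healthy skin. Blood endothelial genes were higher in 8 of 15 cases before (10 adjusted over the list alone) and 5 of 15 after treatment (10 adjusted over the list alone; camera adjusted p = 0.0025 and 2.6e-06; adjusted p = 0.47 and 0.45 with an estimated correlation), with the adhesion molecule gene PECAM1 at 2.58 ± 0.257, 2.30 ± 0.504 and 0.485 ± 0.261 RPKM. In the inflammasome and IL-1 family list 2 of 17 genes were lower after treatment than in healthy skin, IL36B and IL18, and 4 adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.47 with an estimated correlation). IL36B, an IL-1 family cytokine of keratinocytes, was at 0.092 ± 0.046 against 0.466 ± 0.018 RPKM (adjusted p = 8.2e-05). This list call was lost with size factors, quantile normalization and scaled reads plus 1.

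The interferon gamma response list closed 61.0% ± 34.1 (SD over pairs) of its difference to healthy skin and the macrophage list 50.8% ± 39.1. The share was larger for the interferon gamma response list in 5 of 5 pairs, by 10.2 ± 5.73 points (4.41 to 17.7), and the exact two-sided sign-flip permutation p was 0.0625, the smallest that 5 pairs allow. Whether transcripts induced by interferon gamma fell beyond the loss of macrophages stays untested, since these values are the observation that raised the question, FCGR1A belongs to both lists, and macrophages themselves express many interferon gamma response genes.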
